A study of Drosophila melanogaster with 24 samples.

How the data were processed

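CUT&RUN maps the DNA occupied by a protein: ovaries were permeabilised and incubated with a primary antibody, then with pAG-MNase, a micrococcal nuclease that binds the antibody and cleaves the DNA around it, and the released DNA was made into sequencing libraries, per the labels' protocols. The 24 samples were ovaries of Drosophila melanogaster, with 1 sample in each of 24 groups: profiles of Stwl, of BEAF, of IgG and of 6 histone marks, in ovaries labelled WT, bam GKD or stwl GKD. Lists of occupied intervals were used for 3 samples (Stwl in WT, Stwl in bam GKD and BEAF in WT), and the other 21 samples were not analysed here. Each sample was put in its group by its title. The series' design text speaks of duplicates, and whether a list pools duplicates is not given in the sources used here.

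The authors deposited each list as interval coordinates on the dm6 assembly, with chromosome, start and end and no score, fold, p-value, strand or read count. The submitters' processing notes name FastQC 0.11.8, Trim Galore 0.6.6, Bowtie2 2.2.8, SAMtools 1.9, MACS2 2.1.0 and deepTools 3.2.1, and the role and settings of each, the control library and the threshold are not given in the sources used here. The smallest gap between neighbouring intervals was 1001 bp in both Stwl lists and 76 bp in the BEAF list, so nearby intervals appear to have been joined in the Stwl lists only. Read depth is unknown, and a difference in depth between libraries would change how many intervals a list holds and how wide they are. Interval width stood in for strength where a ranking was needed, which is a weaker measure than a score.

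Intervals on arms 2L, 2R, 3L, 3R, 4 and X were used, and those on the Y chromosome were counted separately. Genes came from the annotation table of the Release 6 plus ISO1 MT assembly, the same assembly as dm6, which holds 17861 genes, 13911 of them protein-coding on these arms. The table gives no strand, transcripts or sequence, so exons, introns and promoters could not be told apart. A gene was called bound when an interval overlapped the window of 500 bp to each side of either of its annotated ends. That window replaced the planned promoter window, and the planned tests of head-to-head genes, of transcript starts and of the CGATA motif were not run. Coordinates are 1-based.

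The share of intervals of a list overlapped by at least 1 bp of another list, or of a gene end window, was given with an exact (Clopper-Pearson) 95% interval, which covers counting error only. It was compared with 100000 circular shifts of the intervals within each arm (two-sided permutation test, smallest p 2e-05), and with 10000 shifts in the alternatives and for RNA genes. Classes of intervals or genes were compared by Fisher's exact test (two-sided), with Woolf 95% intervals of the odds ratio and with 0.5 added where a cell was 0. Each of 23 gene lists was tested against all other protein-coding genes in each of the 3 interval lists, with Benjamini-Hochberg adjustment over the 69 tests and a threshold of 0.05. For each list, genes with Stwl at an end in bam GKD only were also set against those with Stwl in WT only, adjusted over 23 tests. Mantel-Haenszel odds ratios were taken over 10 classes of gene length or interval width, with Robins-Breslow-Greenland 95% intervals for gene length and chi-square p values. Intervals and genes are not replicates, neighbouring genes can share 1 interval, and with 1 list per group every test compares these lists, not the conditions.

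The gene lists, the tests of overlap and of gene lists, the rule for named genes and the settings listed first below were fixed before the data were examined. The rule named every nucleoporin, stwl, bam, BEAF-32 and RpS19b, up to 4 members of each further list that passed its test and 5 genes of each of 6 classes of bound genes, ranked by interval width because no score was held. Not every gene so named is reported here. Of the 23 lists, 6 were taken by a pattern of gene symbols, and the cytochrome P450 pattern also took 2 cyclophilins. The pattern of odorant and gustatory receptors also took ionotropic receptors, whose symbols begin with Ir. The proteasome pattern took 48 genes with symbols beginning with Prosalpha, Prosbeta, Rpn or Rpt, and paralogues among them were not separated. The respiratory chain pattern also took ATP synthase genes, whose symbols begin with ATPsyn. The names Bootlegger and rye were not matched to the table. The 2 older symbols Mtor and nos were matched by hand to Mgtor and nanos after a first run had been seen, and results without them are given as an alternative.

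Settings fixed in advance were gene end windows of 250 bp and 1000 bp, an overlap of at least 50% of the shorter interval, interval centres within 250 bp, intervals moved to random gene ends, intervals at gene ends only and a background of genes with any interval. The alternatives that needed a score were not run. Added after the data were seen were the test of genes bound in 1 genotype only, the wider 50% of each list, equal numbers of the widest intervals (5083 each), an interval anywhere in the gene, classes of gene length or interval width, the share of a chromosome covered and the lists without hand-matched symbols. A first run had already shown the gene list results and the test of genes bound in 1 genotype only when these were settled. An interval anywhere in the gene meant an overlap with the annotated gene itself, without the windows beyond its ends. Intervals lying only in those flanks, which the main setting counts, were dropped there. Under that setting a longer gene has more room for an interval, and it was run without classes of gene length.

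Computation used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, Numba 0.67.0 and Matplotlib 3.10.9. The tests were run first on simulated data. For the overlap of Stwl WT with BEAF, 5% of 40 simulations without a relation had p under 0.05, and a planted overlap of 29.7% was found at 29.6%. Simulated BEAF intervals were placed at random along each arm, so this check does not cover lists that both gather at gene ends. For the Stwl WT gene lists over 13911 genes, 2.8% of 500 unrelated lists and all of 200 planted lists passed an unadjusted 0.05. Within gene length classes these shares were 5% of 200 unrelated lists and 100% of 100 planted lists. For genes bound in 1 genotype only, 1.2% of 500 unrelated lists passed. Those lists were random draws from the genes bound in 1 genotype only. They do not cover lists bound almost throughout in WT, such as nucleoporins and ribosomal proteins, where the direction is nearly fixed.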

Results

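Stwl, described in the labels as a transcription factor and encoded by stonewall (stwl), a gene needed to keep germline stem cells, was profiled by CUT&RUN in whole Drosophila ovaries. The labels assign WT ovaries to differentiated stages and bam GKD ovaries to undifferentiated stages. The bam gene encodes a factor that starts germline differentiation. BEAF, a boundary element protein, was profiled in WT ovaries. On the main chromosome arms, the Stwl list of WT held 8576 intervals with a median width of 721.5 bp, covering 11.7 Mb (8.76% of the arms). The Stwl list of bam GKD held 12857 intervals (median 807 bp, 21.5 Mb, 16.2%), and the BEAF list held 5083 (median 236 bp, 1.94 Mb, 1.45%). Each group had 1 list, so no value has a replicate error and the tests compare these lists, not the conditions. Intervals and genes are not replicates, and read depth was unknown.

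The Stwl lists of both genotypes were compared to ask where Stwl sat in ovaries of undifferentiated and of differentiated stages. Stwl lay at an end of 6891 of 13911 protein-coding genes (49.5%) in both genotypes, of 1645 (11.8%) in bam GKD only, and of 861 (6.19%) in WT only. The other 4514 genes (32.4%) had Stwl at neither end in either genotype. A gene bound in both genotypes could have its intervals at different ends. Among the genes with the widest intervals in both genotypes was pan, which encodes the transcription factor of Wnt signalling (58459 bp in WT, 36201 bp in bam GKD). The ecdysone receptor gene EcR (2R, 6087873 to 6169087) had intervals of 23056 bp and 23355 bp. CG6511 and CG33181 carried the widest of all, 72696 bp and 62801 bp in WT, in intervals that also cover the chorion gene clusters on 3L and X.

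Genes with Stwl in bam GKD only were led by CG31815 (44215 bp), CG30429 (28000 bp), saturn (26363 bp), CG42591 (25833 bp) and CG13408 (21605 bp). Each of the first 4 had a WT interval less than 1000 bp away, at 946 bp, 645 bp, 548 bp and 683 bp, and gained a WT call with a window of 1000 bp. Genes with Stwl in WT only were led by CG14434 (16612 bp), LPCAT, a lysophospholipid acyltransferase gene (8645 bp), CG42806 (6489 bp), CG45071 (6262 bp) and hdm, which acts in meiotic recombination (5955 bp). A bam GKD interval lay inside CG14434 and LPCAT, away from their ends, and a window of 1000 bp gave CG14434 a bam GKD call.

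The stwl gene itself (3L, 14402930 to 14409939) had Stwl at an end in both genotypes, but its widest intervals lay at opposite ends. They ran from 14407189 to 14413151 in WT (5963 bp) and from 14389558 to 14403914 in bam GKD (14357 bp), without overlap. The bam gene (3R, 25243039 to 25245109) also had Stwl at an end in both genotypes. Its interval ran from 25245163 to 25250170 in WT (5008 bp) and from 25245195 to 25249755 in bam GKD (4561 bp), beginning beyond the end of bam and reaching across RpS27 and Nup37 into Nup358. A narrower bam GKD interval also lay inside bam. RpS19b (3R, 23932729 to 23933530), a germline paralogue of a small ribosomal subunit protein, had Stwl in WT only, in an interval of 179 bp lying 441 bp from the gene, while the nearest bam GKD interval lay 874 bp away. That call of RpS19b was lost with a window of 250 bp, and with a window of 1000 bp both genotypes had Stwl there.

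**Figure D1:**
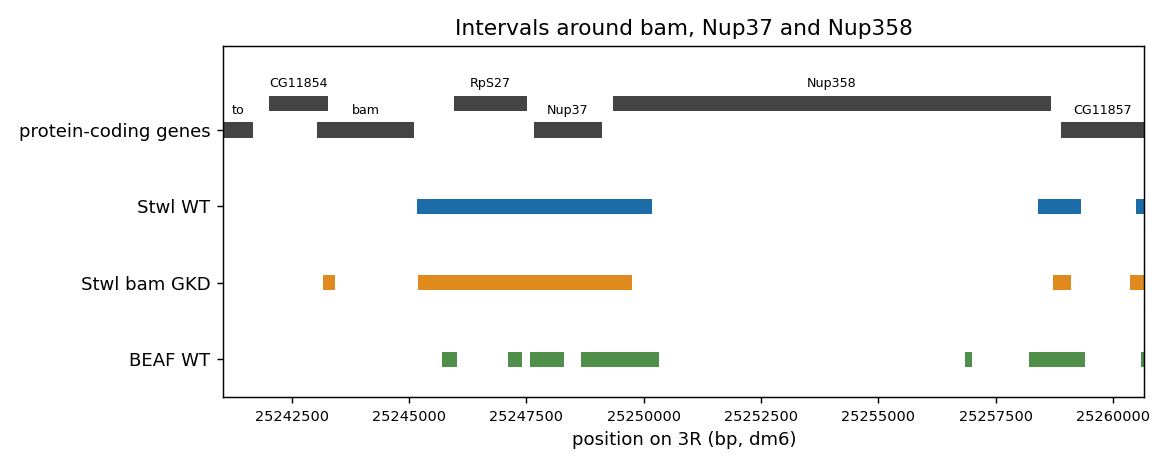
Intervals of Stwl in WT, Stwl in bam GKD and BEAF in WT (coloured bars, 1 list each) along 3R in bp (dm6), with protein-coding genes as grey bars in both upper tracks. A single Stwl interval of 5008 bp in WT and 4561 bp in bam GKD lies beyond the end of bam and reaches Nup37 and Nup358, and the nearest BEAF interval lies 591 bp from bam.

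Of the Stwl intervals of WT, 85.1% (95% interval 84.4 to 85.9) overlapped one of bam GKD, against 27.5% by circular shifts (permutation test, p = 2e-05, the smallest possible). In the other direction 52.1% (51.3 to 53.0) of bam GKD intervals overlapped one of WT, against 17.5% (permutation p = 2e-05). Reads of another library in bam GKD, left open by its intervals at the chorion clusters, would raise these shares and the count of genes bound in both genotypes. The 6154 bam GKD intervals without a WT partner lay at gene ends in 24.5% of cases, and 28.3% of them lay outside genes and gene ends. For the whole bam GKD list the share at gene ends was 47.8%, against 26.6% by circular shifts, and no shifts were made for the unshared intervals alone. The 6703 bam GKD intervals shared with WT lay at gene ends in 69.2% (odds ratio 6.91, 95% interval 6.39 to 7.47). They were wider (median 1297 bp against 512 bp), and a wider interval reaches a gene end more easily. For the overlap of the Stwl lists, intervals moved to random gene ends raised the chance shares to 39.4% and 32.0%. With centres within 250 bp the observed shares of overlap were 41.7% and 27.8%. With equal numbers of the widest intervals the balance turned, to 2264 genes in WT only and 1046 in bam GKD only. Equal numbers cut the WT list at 521 bp and the bam GKD list at 1184 bp, so more of the bam GKD list was dropped. The wider 50% of each list left 5162 genes bound in WT and 5477 in bam GKD, against 7752 and 8536.

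**Figure D2:**
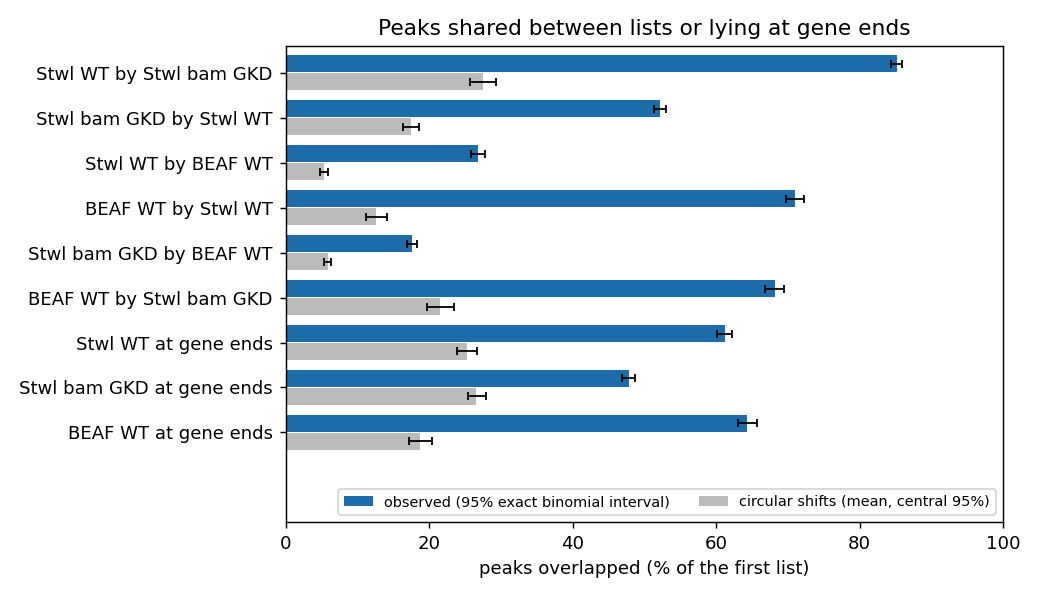
Percent of the intervals of the first-named list that overlap the second list or a gene end (blue bars, with exact binomial 95% intervals) and the mean of circular shifts (grey bars, with the central 95% of shifts). Stwl WT intervals reached 85.1% against 27.5% by shifts, and BEAF WT intervals reached 71.0% with Stwl WT against 12.6%.

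Stwl and BEAF were compared to ask how far the factor shared sites with a boundary element protein in the same tissue. In WT, 3672 genes had both Stwl and BEAF at an end, 4080 had Stwl without BEAF and 238 had BEAF without Stwl. BEAF-32, the gene of BEAF itself (2R, 14770469 to 14772630), was bound in all 3 lists, with intervals of 7383 bp and 7954 bp for Stwl in WT and bam GKD and 2436 bp for BEAF. Stwl without BEAF was found at stwl, bam and EcR, although a window of 1000 bp gave BEAF at bam and a BEAF interval lay inside EcR, away from its ends. BEAF without Stwl WT was led by fs(1)K10, a maternal gene of dorsoventral patterning (2355 bp), CG32225 (2336 bp), CG31817 (2277 bp), Grx5, a glutaredoxin (2027 bp), and CG3328 (1950 bp). The nearest Stwl WT interval lay 16150 bp from fs(1)K10 and between 552 bp and 1253 bp from the others, and a window of 1000 bp gave Stwl WT calls at CG31817, Grx5 and CG3328.

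BEAF overlapped 26.8% (25.9 to 27.8) of Stwl WT intervals, against 5.34% by circular shifts, and Stwl WT overlapped 71.0% (69.8 to 72.3) of BEAF intervals, against 12.6% (both p = 2e-05, permutation test). Across genes the odds ratio of Stwl WT with BEAF was 22.4 (19.5 to 25.7). The IgG and stwl GKD profiles were not analysed here, so background common to the lists could not be separated from shared sites. BEAF intervals with Stwl lay at gene ends in 75.3% of cases and those without in 37.4% (odds ratio 5.12, 4.49 to 5.83). Among genes with Stwl in both genotypes 49.0% had BEAF, against 34.1% of those with Stwl in WT only, 4.80% of those in bam GKD only and 3.52% of those with Stwl in neither. Of bam GKD intervals, those shared with WT overlapped BEAF in 31.9% of cases and the others in 2.01% (odds ratio 22.8, 18.9 to 27.4), with BEAF measured in WT only. Against random gene ends the chance share for Stwl WT with BEAF rose to 14.0%, and that for bam GKD with BEAF rose to 13.4%, against 17.6% observed. The odds ratio across genes was 6.93 with the wider 50% of each list and 8.50 with equal numbers, and that of shared bam GKD intervals was 7.19 with centres within 250 bp.

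Nucleoporin genes were examined because the series concerns nuclear pore formation. Stwl lay at an end of 29 of the 30 nucleoporin genes in WT, against 55.6% of other genes (odds ratio 23.1, 3.15 to 170, adjusted p = 7.82e-06, Fisher's exact test). In bam GKD it lay at 21 of them, against 61.3% of other genes (odds ratio 1.47, 0.673 to 3.21, adjusted exact p = 0.431). BEAF lay at 15, against 28.1% (odds ratio 2.56, 1.25 to 5.25, adjusted exact p = 0.0279). Ndc1, which encodes a membrane nucleoporin, was bound in none of the lists, with the nearest intervals of Stwl WT, Stwl bam GKD and BEAF 988 bp, 894 bp and 833 bp away, all inside a window of 1000 bp. All 3 lists met at 11 genes: Aladin, Gp210, Nup133, Nup153, Nup154, Nup358, Nup37, Nup58, Rae1, Sec13 and mbo.

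Every gene of the outer ring scaffold examined had Stwl in WT: Elys, Nup107, Nup133, Nup160, Nup37, Nup43, Nup44A, Nup75, Nup98-96 and Sec13. So did the basket genes Mgtor, Nup153 and Nup50, the channel genes Nup54, Nup58 and Nup62, and the cytoplasmic face genes Nup214, Nup358 and mbo. Intervals at nucleoporins in WT ranged from 194 bp at Mgtor (2R, 11852629 to 11852822) to 5008 bp at Nup37 and Nup358, with 4189 bp at Nup153 (X, 16607082 to 16611270) and 3005 bp at Nup154 (2L, 11010854 to 11013858). Nup37, Nup358 and bam share 1 interval in each Stwl list.

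Stwl was present at 8 nucleoporin genes in WT only, namely Mgtor, Nup107, Nup35, Nup44A, Nup50, Nup62, Nup75 and Nup93-2, and at none in bam GKD only, against 853 and 1645 other genes (adjusted p = 0.00219, Fisher's exact test, chosen after the data had been seen). BEAF was also present at Mgtor, Nup35, Nup50 and Nup93-2. The nearest bam GKD interval lay 533 bp from Nup93-2, 648 bp from Nup107 and inside Nup44A, but 10799 bp from Mgtor and 18942 bp from Nup62. A window of 1000 bp gave bam GKD calls at Nup93-2, Nup107 and Nup44A, and one of 250 bp removed the WT calls at Nup35 and Nup44A. With 29 of 30 genes bound in WT, at most 1 could have been bound in bam GKD only. Of the genes bound in WT, nucleoporins kept Stwl in bam GKD in 72.4% and others in 89% (odds ratio 0.326, p = 0.0115, Fisher's exact test). Counting an interval anywhere in the gene, which drops those lying only outside its ends, ended the Stwl WT call and turned its odds ratio to 0.911. It left 5 genes in WT only against 1 in bam GKD only (adjusted exact p = 0.192). The wider 50% of each list also ended both (odds ratio 1.70; 7 against 2 genes, adjusted exact p = 0.0885). A background of genes with any interval turned the bam GKD odds ratio to 0.312 (adjusted exact p = 0.0392). All nucleoporins in that background had a Stwl WT interval, so this ratio restates the 8 genes in WT only and is no separate evidence of loss. For BEAF, 4 alternatives ended the call.

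The other 22 gene lists were tested in the same way, against shares of 55.7% of all protein-coding genes bound by Stwl in WT, 61.4% in bam GKD and 28.1% by BEAF. Stwl in WT was more frequent at 12 of all 23 lists, less frequent at 3 and past the threshold at neither side for 8. For Stwl in bam GKD these numbers were 6, 3 and 14, and for BEAF 8, 3 and 12. Ribosomal protein genes stood highest after nucleoporins in WT, with Stwl at 88 of 92 (odds ratio 17.7, 6.48 to 48.2, adjusted p = 1.35e-16, Fisher's exact test). In bam GKD Stwl lay at 77 of them (odds ratio 3.25, 1.87 to 5.66, adjusted exact p = 2.78e-05). BEAF lay at 65 (odds ratio 6.24, 3.98 to 9.80, adjusted exact p = 4.36e-16). RpS3A on 4 (24245 bp in WT), RpS14a and RpS14b on X in a shared interval (9580 bp) and RpS15Aa (9131 bp) had the widest Stwl intervals. Stwl was at 12 ribosomal protein genes in WT only, among them RpL5, RpL11, RpS3 and RpS19b, and at 1 in bam GKD only, RpS10a (adjusted exact p = 0.000527; 849 and 1644 other genes). With 88 bound in WT, at most 4 could have been bound in bam GKD only. Of the genes bound in WT 86.4% kept Stwl in bam GKD against 88.9% of others (odds ratio 0.789, p = 0.397, Fisher's exact test). Counting an interval anywhere in the gene, without the flanks, turned the bam GKD odds ratio from 3.25 to 0.788.

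Mitochondrial ribosomal protein genes were bound at 84.9% in WT (adjusted exact p = 1.85e-06), 80.8% in bam GKD (adjusted p = 0.00183) and 54.8% by BEAF (adjusted p = 1.84e-05). The widest Stwl intervals were at mRpS7 (10207 bp in WT) and mRpL55 (5805 bp). The bam GKD call ended with an interval anywhere in the gene, the wider 50% and equal numbers (odds ratios 1.04, 1.14 and 1.03, against 2.67). The wider 50% also ended the WT call (adjusted exact p = 0.0564), and an interval anywhere in the gene the BEAF call (adjusted p = 0.0929). Cell cycle genes were bound at 91.7%, 86.1% and 66.7%, with odds ratios of 8.77 (2.69 to 28.6), 3.91 (1.52 to 10.1) and 5.14 (2.57 to 10.3; adjusted exact p = 2.78e-05, 0.00624 and 1.44e-05). Of these 36 genes, 21 were in all 3 lists, including the mitotic kinase gene aurA, the checkpoint kinase gene Bub1 and the cyclin gene CycA. The same 3 alternatives ended the bam GKD call of cell cycle genes (odds ratios 1.20, 1.93 and 1.78; adjusted exact p = 0.701, 0.120 and 0.161). Respiratory chain subunit genes were bound at 69.0% in both Stwl lists, past the threshold in WT (adjusted exact p = 0.0279) and not in bam GKD (adjusted p = 0.210), and at 44.8% by BEAF (adjusted p = 0.00413). Within classes of gene length bam GKD passed as well (odds ratio 1.93, adjusted p = 0.0125, Mantel-Haenszel chi-square test), so the genotypes were not set apart there. The wider 50% ended the WT and BEAF calls, and equal numbers the WT call. Proteasome genes passed for BEAF, at 47.9% (adjusted exact p = 0.0109), with Rpn12, Rpn6, Rpn11 and Prosbeta2 the widest, a call that an interval anywhere in the gene ended. The proteasome list held 48 genes taken by symbol pattern, with paralogues not separated. Stwl lay at 66.7% of them in WT (adjusted exact p = 0.206) and 58.3% in bam GKD (adjusted p = 0.733). Classes of gene length brought the WT value past the threshold (odds ratio 2.05, adjusted p = 0.0485, Mantel-Haenszel chi-square test). Heat shock genes passed in none, at 64.7%, 52.9% and 35.3% (adjusted exact p = 0.709, 0.547 and 0.678). None of the Hsp70 genes was bound.

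Genes of the undifferentiated germline and of differentiation were bound by Stwl at 22 of 27 in WT (adjusted exact p = 0.0157) and 23 in bam GKD (adjusted p = 0.0224) and by BEAF at 14 (adjusted p = 0.0220). The widest were hts, which encodes an adducin of the fusome (8810 bp in WT), brat, a translational repressor (8070 bp), and otu, which lies in the X interval of the chorion cluster. The genes nanos, pum and bgcn were in all 3 lists. Oocyte and maternal patterning genes passed for Stwl WT, at 80.6% (adjusted exact p = 0.0148), with 71.0% in bam GKD (adjusted p = 0.431) and 45.2% for BEAF (adjusted p = 0.0763). The widest there were gus (9311 bp), gnu (7621 bp) and osk, whose product builds the germ plasm (6322 bp). The list of SETDB1, HP1 and piRNA silencing factors was bound at 82.1% in WT (adjusted exact p = 0.0119), 78.6% in bam GKD (adjusted p = 0.118) and 39.3% by BEAF (adjusted p = 0.265). Its widest Stwl intervals were at wde (9151 bp), ova (8767 bp) and arx (6870 bp). Classes of gene length ended the Stwl WT calls of these 3 lists and the bam GKD call of the germline list, with odds ratios that fell and stayed above 1 in wide intervals. In WT they went from 3.50 (1.33 to 9.26) to 2.72 (0.990 to 7.47) for the germline list and from 3.32 (1.36 to 8.09) to 2.37 (0.964 to 5.82) for the oocyte list. For the SETDB1 list the change was from 3.66 (1.39 to 9.64) to 3.14 (1.13 to 8.71; adjusted p = 0.0940, 0.0940 and 0.0511, Mantel-Haenszel chi-square test). In bam GKD the germline ratio went from 3.63 (1.25 to 10.5) to 2.71 (0.870 to 8.46; adjusted chi-square p = 0.142). The BEAF call of the germline list was lost without the symbols matched by hand (adjusted exact p = 0.0514) and with a window of 250 bp (adjusted p = 0.0708). An interval anywhere in the gene brought the oocyte list past the threshold in bam GKD and for BEAF (adjusted exact p = 0.0307 and 0.0238), and the SETDB1 list in bam GKD (0.0476). The wider 50% ended the WT call of the oocyte list. Meiotic recombination genes did not pass, at 72.0%, 60.0% and 48.0% (adjusted exact p = 0.162, 1 and 0.0740).

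Insulator and architectural protein genes were bound at 84.0% in both Stwl lists (adjusted exact p = 0.0119 in WT and 0.0441 in bam GKD) and at 68% by BEAF (adjusted p = 0.000224). Of these 25 genes, 14 were in all 3 lists, among them BEAF-32, Cp190, Ibf1 and Ibf2 (which share 1 interval), and the cohesin gene SMC1. Genes of histone lysine methylation and acetylation enzymes were bound at 92.0% in WT (adjusted exact p = 0.000714) and 84.0% in bam GKD (adjusted p = 0.0441), and at 44.0% by BEAF (adjusted p = 0.166). Among them were chm, nej, which encodes the CBP acetyltransferase, and HDAC1. Polycomb and trithorax genes were bound at 85.7% in WT (adjusted exact p = 0.00406), 78.6% in bam GKD (adjusted p = 0.118) and 35.7% by BEAF (adjusted p = 0.477). The demethylase gene Utx had the widest interval (27463 bp). Nuclear transport factors passed in WT, at 18 of 19 (adjusted exact p = 0.00135), and not in bam GKD (16, adjusted p = 0.0928) or for BEAF (10, adjusted p = 0.0665). They included Ntf-2 (5297 bp), Cse1 (3049 bp) and Ran (2717 bp). Nuclear lamina and envelope genes did not pass, at 8, 7 and 6 of 10 (adjusted exact p = 0.262, 0.796 and 0.0649). Classes of gene length ended the Stwl WT calls of the insulator and Polycomb lists and the bam GKD calls of the insulator list and of the histone enzymes, again with lower odds ratios above 1. In WT they went from 4.18 (1.43 to 12.2) to 2.86 (0.966 to 8.45) for insulators and from 4.78 (1.66 to 13.8) to 3.06 (1.03 to 9.08) for Polycomb genes (adjusted p = 0.0940 and 0.0789, Mantel-Haenszel chi-square test). In bam GKD they went from 3.31 (1.14 to 9.65) for either list to 2.40 (0.839 to 6.87) for insulators and 2.08 (0.726 to 5.98) for histone enzymes (adjusted chi-square p = 0.141 and 0.217). The wider 50% and equal numbers ended these same bam GKD calls, and the WT calls of the histone enzymes and transport factors. An interval anywhere in the gene also ended the bam GKD call of the histone enzymes, which held in 2 of 6 alternatives. A window of 250 bp brought transport factors past the threshold in bam GKD and for BEAF (adjusted exact p = 0.0384 and 0.0296) and lamina genes for BEAF (0.0431). The Polycomb list passed in bam GKD with an interval anywhere in the gene (adjusted exact p = 0.0476), and lamina genes passed in WT with the wider 50% (0.0264).

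Receptor genes of chemosensory neurons were the least often bound of all 23 lists by each protein. Stwl lay at 10.6% of the 179 odorant, gustatory and ionotropic receptor genes in WT and 26.3% in bam GKD, and BEAF at 5.03%. The odds ratios were 0.0921 (0.0572 to 0.148), 0.220 (0.157 to 0.307) and 0.133 (0.0682 to 0.261, adjusted exact p = 2.57e-35, 4.35e-20 and 4.19e-14). Stwl was at 34 of them in bam GKD only and at 6 in WT only, a balance that did not pass (adjusted exact p = 0.0825). Cytochrome P450 genes were bound at 38.8% in WT (adjusted exact p = 0.00696) and 9.41% by BEAF (adjusted p = 0.000248), and at 54.1% in bam GKD (adjusted p = 0.240). Cyp4ac3 and Cyp311a1 were among those in all 3 lists. Spermatogenesis genes were bound at 29.0% in WT (adjusted exact p = 0.0109), 38.7% in bam GKD (adjusted p = 0.0312) and 16.1% by BEAF (adjusted p = 0.221). Of these, gdl, mia, vis and bol were bound by Stwl in both genotypes. Classes of gene length ended the bam GKD call (odds ratio 0.397, 0.192 to 0.818, before and 0.493, 0.235 to 1.04, after; adjusted p = 0.106, Mantel-Haenszel chi-square test), equal numbers ended both Stwl calls, the wider 50% the WT call and a window of 250 bp the bam GKD call. Homeotic and segmentation genes were low in bam GKD, at 35.5% (adjusted exact p = 0.0126), and for BEAF, at 6.45% (hh and ey; adjusted p = 0.0126), with 38.7% in WT (adjusted p = 0.112). Within classes of gene length they were low in WT as well (odds ratio 0.334, adjusted p = 0.00886, Mantel-Haenszel chi-square test). The wider 50% and an interval anywhere in the gene ended the bam GKD and BEAF calls, and equal numbers the bam GKD call. With the window of 500 bp and no length classes, no list passed for neuronal genes (51.9%, 66.7% and 11.1%; adjusted exact p = 0.757, 0.757 and 0.0900), muscle genes (35%, 65.0% and 25.0%; 0.114, 0.859 and 1) or follicle cell and chorion genes (75%, 71.9% and 25.0%; 0.0611, 0.347 and 0.870). Classes of gene length brought Stwl WT past the threshold for muscle genes, as less frequent, and for follicle cell and chorion genes, as more frequent (odds ratios 0.280 and 2.58, adjusted p = 0.0113 and 0.0142, Mantel-Haenszel chi-square test). A window of 250 bp did so for muscle genes in WT and neuronal genes for BEAF (adjusted exact p = 0.00848 and 0.0488), both lower. In the follicle cell and chorion list, Cp15, Cp16, Cp18 and Cp19 shared 1 Stwl WT interval. The genes Cp7Fa, Cp7Fb, Cp7Fc, Cp36 and Cp38 shared another, so the value for that list counts few intervals as many genes. An interval anywhere in the gene made neuronal genes higher in bam GKD and for BEAF (adjusted exact p = 0.000729 and 0.0446). That setting gives longer genes more room for an interval and was run without classes of gene length. With the window of 500 bp, such classes took the neuronal odds ratios from 1.26 to 0.618 in bam GKD and from 0.319 to 0.287 for BEAF. Over all alternatives run, 4 of the 15 Stwl WT calls, 1 of the 9 bam GKD calls and 5 of the 11 BEAF calls held in every one. Those were the cell cycle, ribosomal, receptor and P450 calls in WT, the receptor call in bam GKD, and these same 4 lists and the insulator list for BEAF.

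**Figure D3:**
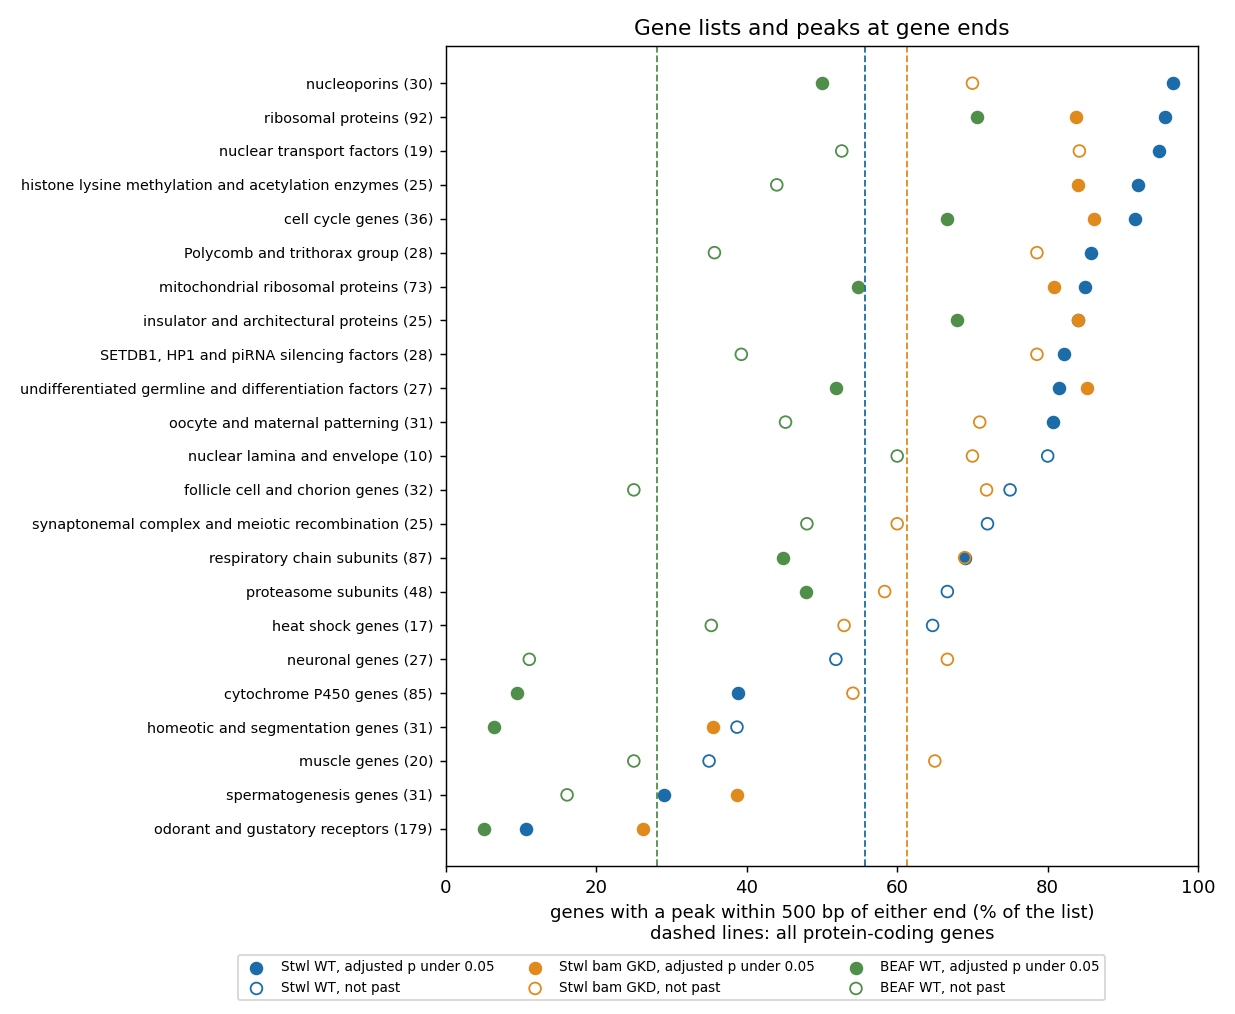
Percent of the genes of each of 23 lists (number of genes in brackets) with an interval within 500 bp of either end, for Stwl WT (blue), Stwl bam GKD (orange) and BEAF WT (green); filled points passed an adjusted p of 0.05, open points did not, and dashed lines give the share of all protein-coding genes. Nucleoporins stood at 96.7% for Stwl WT and 70.0% for bam GKD, and receptor genes at 10.6% and 26.3%.

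By chromosome, BEAF was denser on X, with 68 intervals per Mb against 31.1 on the arms of 2 and 3 (ratio 2.19, 2.06 to 2.33), and 39.7% of BEAF intervals without Stwl WT lay on X, against 27.5% of those with it. Stwl differed less on X (ratio 1.16, 1.10 to 1.22, in WT and 1.15, 1.10 to 1.21, in bam GKD). Chromosome 4, which is small and rich in heterochromatin, was covered to 62.2% by Stwl in WT and 72.0% in bam GKD, against 7.65% and 14.6% of the arms of 2 and 3. All of its protein-coding genes, among them pan, ey, pho and RpS3A, were bound by Stwl in both. Its interval density relative to the arms of 2 and 3 was 2.15 (1.85 to 2.51) in WT, 1.08 (0.906 to 1.28) in bam GKD and 3.18 (2.66 to 3.80) for BEAF. With the wider 50% of each list the density ratios on 4 were 3.39 in WT and 1.75 in bam GKD. Ratios of coverage, measured with all intervals, were 8.14 and 4.93.

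**Figure D4:**
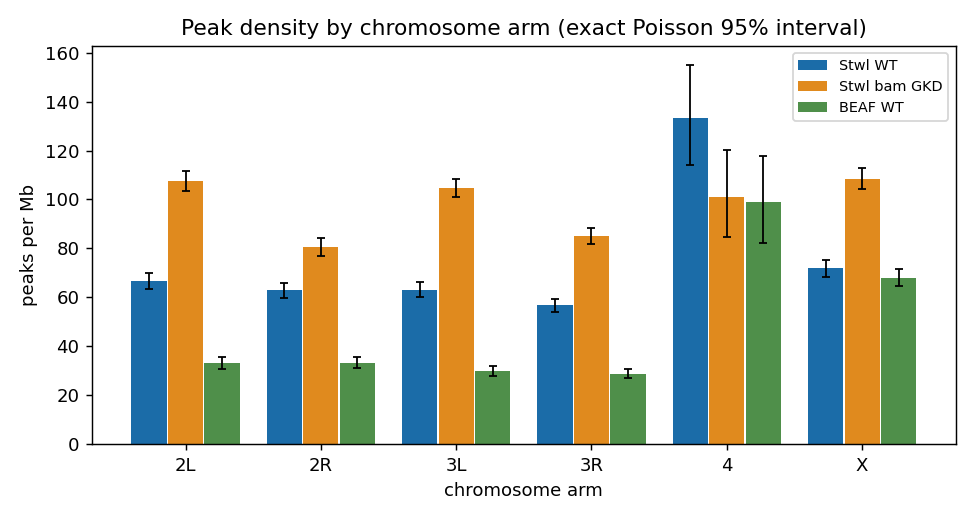
Intervals per Mb on each chromosome arm for Stwl WT (blue), Stwl bam GKD (orange) and BEAF WT (green), with exact Poisson 95% intervals that cover counting error only. BEAF stood between 28.8 and 33.3 per Mb on the arms of 2 and 3, at 68 on X and at 98.8 on 4, and Stwl WT reached 133 on 4.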

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

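The comparisons of genes bound in 1 genotype only and the nucleoporin tests of interval width and of shared intervals were chosen after the results were seen; the same tests of ribosomal protein genes were set before their values were seen.

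The 2 Stwl lists, 1 per genotype, parted at nucleoporin genes, with 8 in WT only and 0 in bam GKD only (odds ratio 0.0305, adjusted p = 0.00219, Fisher's exact test), and at ribosomal protein genes, with 12 and 1 (odds ratio 0.0430, adjusted p = 0.000527), but with 29 of 30 and 88 of 92 bound in WT the direction was nearly fixed beforehand, and no difference between the conditions can be called. Loss of weak intervals at the peak threshold stays open. Among genes with WT intervals of like width fewer kept Stwl in bam GKD. The Mantel-Haenszel odds ratios were 0.357 for nucleoporins (chi-square p = 0.0125) and 0.442 for ribosomal protein genes (chi-square p = 0.0165). Without width classes the ribosomal ratio was 0.789 (p = 0.397, Fisher's exact test). These ratios cannot decide it, because both sets of genes were picked for their loss between the same 2 Stwl lists. Interval width is also a weaker measure than a score. A lost interval counted for several neighbours is argued against by the 8 distinct WT intervals behind the 8 nucleoporin genes and the 12 behind the 12 ribosomal protein genes. Differences in depth and in how the lists were made stay open because the lists hold no read counts. A stage-dependent gain of Stwl at these genes may also account for the pattern and stays untested with 1 list per genotype, and counting an interval anywhere in the gene left the nucleoporin odds ratio at 0.153 (adjusted exact p = 0.192), and the wider 50% left it at 0.226 (adjusted p = 0.0885).

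Outside the arms compared, on the Y chromosome, the lists held 9 intervals for Stwl WT, 31 for Stwl bam GKD and 9 for BEAF WT.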

How the results depend on the processing

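No paired analysis was possible because each group had 1 list and no replicate numbers. All overlap shares stayed above chance, shares of intervals at gene ends stayed between 44.5% and 72.5%, and the odds ratios across intervals and genes stayed above 1 in every alternative that applied to them. Alternatives by score, transcript start, head-to-head distance and motif window were not run, as the data used hold no score, strand or sequence; the wider 50%, equal numbers, an interval anywhere in the gene, classes of gene length and hand-matched symbols were chosen after seeing the data. Genes bound fell with the wider 50% to 5162 in WT and 5477 in bam GKD, and with equal numbers to 4663 in bam GKD, where fewer intervals were used by construction. With equal numbers the genes in WT only rose from 861 to 2264 and those in bam GKD only fell from 1645 to 1046. That setting kept Stwl intervals down to 521 bp in WT and down to 1184 bp in bam GKD, so it cut the bam GKD list harder by construction. For nucleoporins, an interval anywhere in the gene gave odds ratios of 0.911 (WT), 0.459 (bam GKD) and 1.44 (BEAF) and 0.153 for 1 genotype only; the wider 50% gave 1.70, 0.770, 2.43 and 0.226. The bam GKD ratio was 0.721 with equal numbers and 0.312 against genes with any interval, and the BEAF ratio 1.55 against genes with any interval and 1.99 within length classes. All nucleoporins with any interval had one of Stwl WT, so the 0.312 restates the genes in WT only. Other lists turned direction, past the threshold for BEAF at neuronal genes only. With an interval anywhere in the gene the ratios were 0.936 for meiotic genes (WT), 2.39 and 2.70 for neuronal genes (WT and BEAF, the latter at adjusted exact p = 0.0446), 1.12 for muscle and 0.448 for heat shock genes (BEAF), and 0.788 for ribosomal and 0.956 for respiratory genes (bam GKD). With the wider 50% they were 1.40 for follicle and 1.05 for muscle genes (BEAF) and 0.941 for respiratory genes (bam GKD). With equal numbers they were 0.944 for oocyte and 0.992 for respiratory genes (bam GKD) and 1.09 for neuronal genes (WT). Within length classes they were 0.990 for Polycomb and 1.02 for follicle genes (BEAF), and 0.618 for neuronal, 0.718 for muscle and 1.15 for proteasome genes (bam GKD); a window of 1000 bp gave 1.12 for meiotic genes (bam GKD). An interval anywhere in the gene gives longer genes more room and was run without length classes, so its turns may reflect gene length. The cause of the turns was not tested. Of the named genes' calls, 23 moved with a window of 1000 bp and 6 with 250 bp. Unknown depth limits the lists: a site absent from a list is not shown to be unoccupied.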

Other observations

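Every test of RNA genes and of the chorion clusters was chosen after the results were seen, except the test that moved Stwl intervals to random gene ends, which was set before its value was seen.

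Genes for short RNAs, outside the protein-coding comparisons, differed by class. Stwl overlapped 193 of 290 tRNA genes in WT (66.6%, 95% interval 60.8 to 72.0, against 8.29% by circular shifts, adjusted p = 0.0005, permutation test over 15 comparisons) and 61.0% in bam GKD (chance 15.0%, adjusted p = 0.0005). BEAF overlapped 3 of them (1.03%, chance 1.57%, adjusted permutation p = 0.847). Counting the tRNA genes as 174 loci merged within 1 kb gave 60.9%, 59.8% and 1.72%. The snRNA genes of the spliceosome were overlapped in all 3 lists, at 37.5% in WT, 40.6% in bam GKD and 25.0% by BEAF (32 genes, adjusted permutation p = 0.00171, 0.0265 and 0.0005), and the 269 snoRNA genes at 34.6%, 32.7% and 8.55% (adjusted p = 0.0005, 0.00225 and 0.00333). The 260 miRNA genes were overlapped at 17.3% in WT (chance 9.45%, adjusted permutation p = 0.00750), 18.5% in bam GKD (chance 17%, adjusted p = 0.808) and 2.31% by BEAF (chance 1.87%, adjusted p = 0.816).

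The tRNA pattern parts Stwl from BEAF. Assay background strong enough to give intervals at tRNA genes in every list is argued against by the BEAF share of 1.03%, inside its range by chance of 0 to 3.79%. Background too weak to be called in the BEAF list stays open, as that list appears to have been made differently and its depth is unknown. A place of tRNA genes among other gene ends is argued against too: Stwl WT intervals moved to random gene ends overlapped 8.78% of tRNA genes on average (central 95% 4.83 to 13.4), and none of 2000 draws reached the observed 66.6% (permutation p = 0.001, the smallest possible). Background of the Stwl antibody alone, or of wider intervals than those of BEAF, stays open, as the Stwl profile of stwl GKD and the IgG profile were not analysed here. No biological explanation was tested, and Stwl at tRNA genes may be examined as a hypothesis in those profiles.

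The widest Stwl intervals lay at the chorion gene clusters, which are known to be amplified in follicle cells: at Cp15, Cp16, Cp18 and Cp19 (3L, 8688702 to 8761397, 72696 bp in WT and 81541 bp in bam GKD, rank 1 in both) and at Cp7Fa to Cp38 (X, 8463044 to 8525844, 62801 bp, rank 2 in WT, and 50884 bp, rank 3 in bam GKD). Transcription of late follicle cell genes stays open: the narrowest cluster interval was 6.95 times as wide as the widest at 9 other such genes (7322 bp in bam GKD, at Fcp3C, the lower ratio of both Stwl lists), but the clusters were picked for their width, which fixes that outcome. Higher DNA copy number may account for it: BEAF, another protein, covered 41.8% of the 100 kb around the 3L cluster and 16.3% around the X cluster, at percentiles 99.98 and 99.82 of such windows (median 0.623%), though true BEAF sites there would give the same. Whether those in bam GKD, labelled undifferentiated, come from that tissue or from reads of another library cannot be told apart, as the intervals were 1.12 times the width of WT at 3L and 0.810 times at X, on both sides of equality. Read counts of an IgG or input library over these windows would test the copy number hypothesis.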
